A study of Homo sapiens with 4 samples.

How the data were processed

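RNA was measured in SK-N-BE(2)C, an established neuroblastoma cell line with amplified MYCN, after 144 h with 10 µM all-trans retinoic acid (ATRA) or with ethanol, its solvent. There were 2 libraries per group. Per the labels' protocols, cells were lifted with versene, total RNA was column purified, ribosomal RNA was depleted and libraries were made with a directional kit. The depletion kit leaves small structured RNAs such as 7SL in the library, and residual ribosomal RNA can differ between preparations.

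The deposited table holds raw read counts per gene symbol for 55765 symbols, with no blank names and no total rows. Per the submitters' processing notes, STAR 2.5.2b and featureCounts 1.5.1 were named together with the human build hg19. The annotation, the strand setting and the treatment of reads shared by several genes are not given in the sources used here. Reads of overlapping, antisense or near-identical genes are therefore uncertain in these counts, and no coordinates are printed. Gene types and gene order came from GENCODE 29 and RefSeq tables of a later build, used only for names, types, order and transcript sequence. A type was found for 35516 of the symbols (63.7%), and symbols with no type took between 1.15% and 1.56% of the counts of a library. Of the list members, PECAM1 had no match and was not analysed here, and 3 members were found under an older symbol.

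The comparison of ATRA with ethanol was fitted with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its default minimum count of 10, counts were scaled by TMM, and the quasi-likelihood F test with robust estimation was applied with the treatment group as the sole term, which leaves 2 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 18900 genes that passed the filter, with a threshold of 0.05, and all tests were two-sided. Fold changes are log2 values of ATRA over ethanol. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM computed from the deposited counts on TMM-scaled library sizes, given as mean ± SD with n = 2 per group. Differences within libraries of the same replicate number were computed from log2 CPM with a prior count of 2. Where the lower group held no read, the fold is a lower bound against 3 counts over that group. With 1 to 3 reads, the ratio of counts is given with its 95% exact counting interval. These bounds and intervals cover counting error only, since reads carried no molecular identifiers.

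The following choices were made before the data were examined: the tests, 30 gene lists, and the rule for naming genes. Genes are named if they are among the 10 largest rises or 10 largest falls past the threshold among protein-coding genes with a gene symbol, a mean log2 CPM of at least 3 and both ATRA libraries on the same side of both ethanol libraries. A set of genes with known roles in retinoid response and neuroblastoma is named whatever its values, of which 19 are given; results for a few genes that this rule names are not reported here. From each list up to 2 members called in each direction are named, or the 2 with the smallest p where none was called, given a mean log2 CPM of at least 1. Other genes were chosen after their values were seen, which is stated where it applies. The lists were tested with camera in limma 3.58.1 with its preset correlation of 0.01, and camera with an estimated correlation and fry stand beside it. Benjamini-Hochberg adjustment covered the 30 lists. List counts are given over all genes tested and, separately, adjusted over the list alone.

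The lists cover retinoid targets, retinoid receptors and metabolism, HOX genes, adrenergic transcription factors, mesenchymal genes, catecholamine synthesis and storage, cholinergic genes, neuronal cytoskeleton and neurite growth, synapse and vesicle release, neurotrophin and GDNF family receptors, axon guidance, voltage-gated ion channels, and markers of Schwann cell precursors, chromaffin cells and sympathoblasts. They also cover G1/S genes, G2/M genes, cell cycle inhibitors, MYC targets with ribosome biogenesis, the BCL2 family with cell death, collagens, matrix and integrins, antigen presentation with interferon response, cholesterol synthesis, and the unfolded protein with integrated stress response. The rest hold Wnt, Notch, BMP and hedgehog signalling, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, stress and immediate early genes, and markers of other cell types.

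The procedure was tested on counts simulated for the 18900 genes, with the library differences seen here, made the same in both groups. Of the simulated genes, 18379 passed the filter. Between ATRA and ethanol 100 genes were changed 2-fold and 100 changed 8-fold, all drawn from genes with a mean above 1 CPM. The procedure recovered 0% of the 2-fold and 52% of the 8-fold changes, with 0 false calls. In a second simulation the library differences were not shared between groups, but their spread entered as random noise between libraries of a group. There, with 18091 genes past the filter, it recovered 2% and 67% with 10 false calls, which was 12.7% of its calls. Each simulation was a single draw, so its share of false calls need not hold for the data. Changes of about 2-fold were thus mostly out of reach of this test.

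Alternatives set before the data were examined were other scalings (RLE, upper quartile, library size), other filters, DESeq2 1.42.0, limma-voom, a test without robust estimation, glmTreat against a log2 fold change of 1, protein-coding genes alone, removal of mitochondrially encoded genes with the 20 most abundant genes, the title suffix as a block, and leaving out each library in turn. DESeq2 with that block was added after the data were seen. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the permutations and figures.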

Results

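The series measured gene expression in SK-N-BE(2)C neuroblastoma cells kept for 144 h with 10 µM ATRA, the acid form of vitamin A that drives neuroblastoma cells to differentiate, or with its solvent ethanol. There were 2 libraries per group. Total counts were 15518828 and 16498355 for ATRA replicates 1 and 2, and 12850462 and 19883465 for ethanol replicates 1 and 2. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

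Libraries also differed by the number in their titles. Mitochondrial ribosomal RNA took 2.485% and 5.96% of counts in the libraries without a number (ATRA 1 and ethanol 1), and 0.130% and 0.0291% in those numbered 2. Protein-coding genes took 75.8% and 75.7% against 86.9% and 86.9%. The first principal component, with 55.6% of the variance, parted ATRA from ethanol, and the second, with 36.7%, parted the replicate numbers. Across genes, which are not independent replicates, log2 CPM correlated at 0.948 between the ATRA libraries and 0.947 between the ethanol libraries, and between treatments at 0.908 within replicate 1 and 0.944 within replicate 2. Because the libraries part by replicate number as well, log2 differences within replicate 1 and within replicate 2 are given beside the main values.

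**Figure D1:**
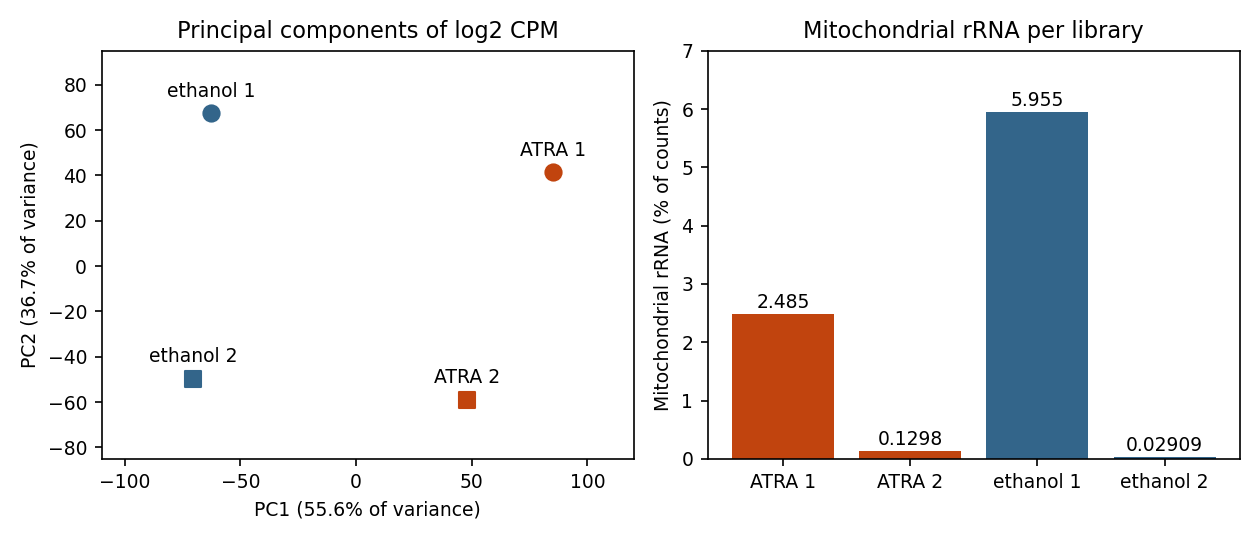
Left, the first and second principal components of log2 CPM with 1 point per library, circles for replicate 1 and squares for replicate 2. Right, mitochondrial ribosomal RNA as a percent of all counts, with 1 bar per library; the replicate 1 libraries stand at 2.485% and 5.96%, and both replicate 2 libraries stand below 0.2%.

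Does ATRA change the transcriptome of these cells, and which genes respond? The enzymes that break down retinoic acid rose from next to nothing. CYP26A1 reached 204 ± 90.0 CPM (SD, n = 2) with ATRA and had 0 reads in both ethanol libraries, so it was at least 2294-fold higher. CYP26B1 reached 47.2 ± 32.7 CPM against 1 read with ethanol, a ratio of 1613 with a counting interval of 289.1 to 63760. The gap junction gene GJA5 had a ratio of 1561 (counting interval 279.7 to 61680) and the succinate receptor gene SUCNR1 a ratio of 707 (241.5 to 3430). The largest falls were DLK1, a membrane protein of chromaffin cells (721 ± 149 to 7.92 ± 3.44 CPM), SORBS2, and the serotonin receptor HTR3A.

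In all, 132 of 18900 genes passed the threshold, 103 higher and 29 lower with ATRA (edgeR quasi-likelihood, Benjamini-Hochberg), and 3009 had an unadjusted p under 0.05. All 132 had an absolute log2 fold change of at least 1, the smallest being 1.73. By type, 113 were protein-coding. The log2 differences within replicate 1 and within replicate 2 correlated at 0.743 across genes. The count depends strongly on the test: DESeq2 called 1269 genes, limma-voom 50, and fits without 1 of the 4 libraries between 870 and 1442.

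Among the other large rises were KIAA1244 at log2 8.51 ± 0.42 (SE), FAM20C at 6.98 ± 0.78, ODAM at 6.40 ± 0.80, the fibrillar collagen COL3A1 at 6.36 ± 0.85, DHRS3 at 6.22 ± 0.74 and SAMD9L at 6.14 ± 0.54. Their adjusted p lay between 0.0082 and 0.0459 (edgeR quasi-likelihood). COL3A1 varied between libraries, with 112 CPM in ATRA 1 and 27.7 CPM in ATRA 2, and it was not called without ethanol replicate 1 (adjusted p 0.160, edgeR quasi-likelihood). SUCNR1 was likewise not called without ethanol replicate 1 (adjusted p 0.268, edgeR quasi-likelihood). The falls included DLK1 at -6.51 ± 0.46, SORBS2 at -6.21 ± 0.77, HTR3A at -6.19 ± 0.54, the homeobox gene LHX9 at -4.61 ± 0.56 and CHODL at -4.48 ± 0.48. PTPRU, SPOCK3, IGFBP7, GRIK3 and SULF2 fell by 4.25, 4.13, 3.77, 3.70 and 3.61 on the log2 scale. DLK1 fell within both replicates, with log2 differences of -6.78 and -6.30, and SULF2 with -3.39 and -3.78.

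Of the 19 genes reported here that were chosen before the data were examined, 5 passed the test: CYP26A1, CYP26B1, DHRS3, RARB and GATA3. RARB, a retinoic acid receptor that is itself a retinoid target, rose from 1.66 ± 0.17 to 50.6 ± 23.0 CPM (log2 4.92 ± 0.46, adjusted p 0.0319, edgeR quasi-likelihood; 4.38 and 5.13 within replicates). DHRS3, a retinaldehyde reductase, rose from 0.237 ± 0.226 to 19.7 ± 8.38 CPM. GATA3, a transcription factor of the sympathoadrenal lineage, fell from 40.7 ± 2.73 to 6.53 ± 1.09 CPM (-2.73 and -2.53 within replicates). The receptor tyrosine kinase gene RET was at log2 1.52 ± 0.27 and RARA at 1.52 ± 0.28, with adjusted p 0.0709 and 0.0760 (edgeR quasi-likelihood). MEIS1 and SOX4 were at 1.76 ± 0.34 and 1.75 ± 0.38.

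MYCN, the amplified oncogene of this line, had 3325 ± 586 CPM with ethanol and 2048 ± 382 CPM with ATRA, a log2 difference of -0.70 ± 0.31 that did not pass (adjusted p 0.345, edgeR quasi-likelihood; -0.69 and -0.71 within replicates). HAND2 was at -0.30 ± 0.24 and ISL1 at -0.06 ± 0.24. TH and DBH, enzymes of catecholamine synthesis, were at -0.38 ± 0.46 and -0.79 ± 0.54. The neuronal genes STMN2 and GAP43 were at 0.77 ± 0.56 and 0.99 ± 0.37. MKI67, a marker of cycling cells, was at -1.25 ± 0.49, and the inhibitor gene CDKN1A at 0.52 ± 0.48. NTRK2 had 61 reads with ATRA and 2 with ethanol, a ratio of 32.1 with a counting interval of 8.524 to 271.4, and did not pass. No gene in this paragraph passed (edgeR quasi-likelihood adjusted p of 0.150 or more).

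**Figure D2:**
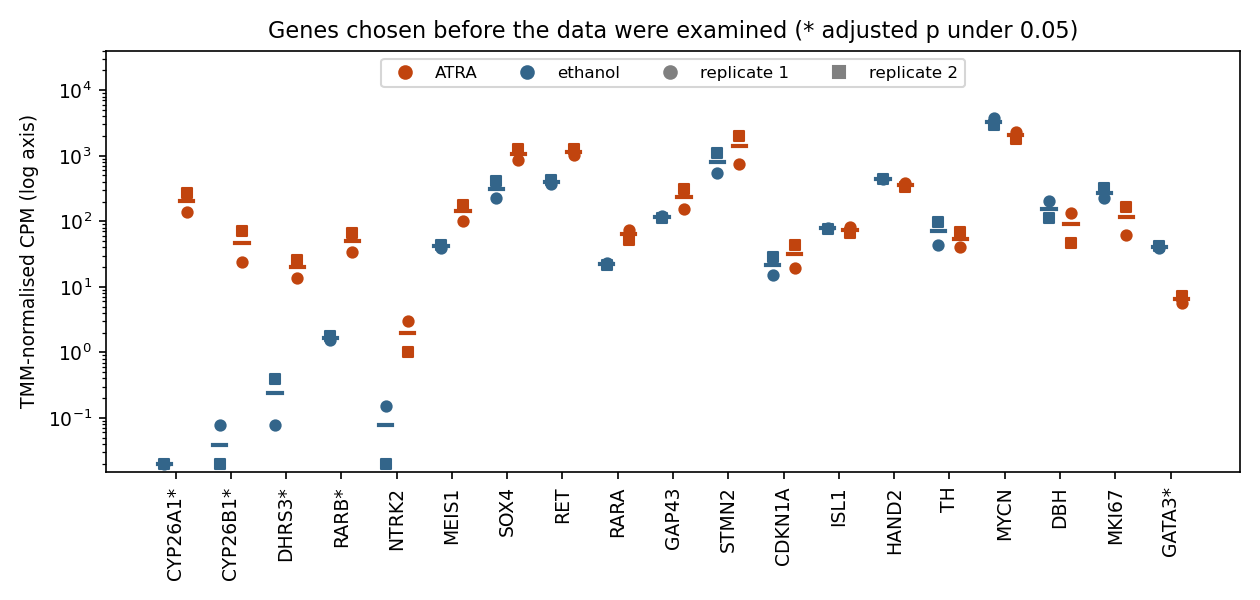
TMM-normalised CPM on a log axis for 19 genes chosen before the data were examined, with 1 point per library, short bars for group means, and asterisks for genes with adjusted p under 0.05. Values of 0 are drawn at the lower edge, as for CYP26A1 in both ethanol libraries; GATA3 lies lower in both ATRA libraries and RARB higher.

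Which gene programmes moved? Camera with its preset correlation called 14 of the 30 lists, 8 higher and 6 lower with ATRA. With an estimated correlation camera called 0 lists, with adjusted p from 0.273 to 0.891. That form works on the 2 residual degrees of freedom, so it could hardly call any list here. For the retinoid targets the estimate was -0.0295, below the preset 0.01, and adjusted p was still 0.273. Large p-values from it thus decide nothing. Among the lists called, the estimate was highest for G1/S genes (0.855), G2/M genes (0.752), ribosomal proteins (0.499), neuronal cytoskeleton (0.447) and histones (0.303). It was also above the preset for HOX genes (0.208), the matrix list (0.128), synapse genes (0.123), mesenchymal genes (0.0758) and the BCL2 family (0.0448). For all of these lists the preset p is likely too small. The other lists called had estimates below the preset. Fry called 1 list as moving one way, the retinoid targets (adjusted p 0.0141), and 22 lists as changing in either direction. The list calls below therefore rest on the preset correlation. Counts of members called singly moved with the setting in most lists, as the total did. For the lists called, counts in the direction of the list are also given without each library in turn, in the order ATRA 1, ATRA 2, ethanol 1 and ethanol 2, where they moved by over 1.5 times (edgeR quasi-likelihood). Those fits called far more genes in all than the main test, so larger list counts in them are no added support.

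The retinoid targets rose as a group. Of 14 measured members, 5 rose and 0 fell (9, 10, 9 and 9 rose without a library), 10 rose adjusted over the list alone, and all 14 were higher within both replicate numbers. The median log2 fold change was 2.82, with 3.27 and 2.34 within replicates (camera adjusted p 4.73e-11; adjusted p = 0.273 with an estimated correlation). CYP26A1 and CYP26B1 led. HIC1, a zinc finger repressor named after its values were seen, was the other member called besides DHRS3 and RARB. Among retinoid receptors and metabolism genes, 0 of 25 passed and 1 was higher adjusted over the list alone (median 0.48, camera adjusted p 0.0680; 0.0354 without ATRA replicate 1, 0.0137 without ethanol replicate 2 and 0.0395 with every gene of at least 1 count). RDH10, a retinol dehydrogenase, was at 2.03 ± 0.32.

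HOX genes were higher as a list (median 1.07; camera adjusted p 0.000102; adjusted p = 0.435 with an estimated correlation), and 12 of 14 measured members were higher within both replicates. HOXD10 rose by 3.44 ± 0.47, and 5 rose adjusted over the list alone; without a library 2, 3, 1 and 2 members rose. The call of HOXD10 ended with library size alone as the scaling (adjusted p 0.0506, edgeR quasi-likelihood).

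The extracellular matrix list was higher. Of 63 collagens, matrix proteins and integrins, 5 rose and 0 fell, and adjusted over the list alone 31 rose and 1 fell. The 5 became 17, 31, 15 and 25 without a library, 26 with DESeq2, 33 with every gene of at least 1 count, and 2 with limma-voom and with glmTreat; the 0 became 1, 2, 1 and 2 without a library. The median was 1.33, with 1.56 and 1.13 within replicates (camera adjusted p 2.25e-09; adjusted p = 0.435 with an estimated correlation). COL3A1 led, followed by the integrin subunit ITGA3 at 5.49 ± 0.64 (0.954 ± 0.719 to 41.2 ± 14.6 CPM). Mesenchymal genes were higher too (median 1.09; camera adjusted p 2.63e-05; adjusted p = 0.435 with an estimated correlation), with 2 of 31 members called and 14 higher adjusted over the list alone. The 2 became 4, 12, 7 and 11 without a library, 12 with DESeq2, 14 with every gene of at least 1 count and 1 with glmTreat. Fibronectin, FN1, rose from 27.8 ± 8.54 to 573 ± 154 CPM, and vimentin, VIM, rose by 2.86 ± 0.34. FN1 belongs to both lists. In the list of markers of other cell types, 0 of 14 measured members passed (camera adjusted p 0.0802; 0.00565 without ATRA replicate 1), and 5 were higher and 1 lower adjusted over the list alone. Smooth muscle actin, ACTA2, was at 3.54 ± 0.78 and KRT8 at 2.92 ± 0.70.

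Neuronal genes moved in part. Of 39 neuronal cytoskeleton and neurite genes 1 rose, STMN4, a stathmin of neurons, by 3.84 ± 0.42, and 14 rose and 1 fell adjusted over the list alone; without a library 14, 6, 7 and 9 rose. The median was 0.69, with 0.50 and 1.05 within replicates (camera adjusted p 1.1e-06; adjusted p = 0.485 with an estimated correlation). Of 42 synapse and vesicle release genes 1 rose, the scaffold gene DLG2, by 5.34 ± 0.38 (9.22 ± 3.35 to 377 ± 34.0 CPM), and 4 rose adjusted over the list alone; without a library 5, 8, 5 and 4 rose. In both lists 1 or more members were called lower without ATRA 2 or ethanol 2, and in the synapse list also without ethanol 1. With every gene of at least 1 count, 8 synapse genes were called higher and 3 lower. The synapse list was higher with a median of 0.41 (camera adjusted p 0.0119; adjusted p = 0.493 with an estimated correlation). Without ATRA replicate 2 neither list was called (camera adjusted p 0.0646 and 0.158), nor was the synapse list without ethanol replicate 2 (0.0762). The sympathoblast markers were not called (median 0.38, camera adjusted p 0.0802; 0.0216 without ATRA replicate 1), although STMN4 rose and 6 rose and 3 fell adjusted over the list alone; 9 members belong to the neuronal list as well.

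Voltage-gated ion channels had 3 of 45 members higher, with KCNA3 at 2.59 ± 0.27 and KCNMA1 at 2.29 ± 0.31, and 7 rose and 3 fell adjusted over the list alone, while the list was not called (camera adjusted p 0.0802; 0.0429 without ATRA replicate 1 and 0.0498 without ethanol replicate 2). SORCS2, a sortilin-related receptor, rose by 2.53 ± 0.30 as 1 of 25 neurotrophin and GDNF family receptor genes, and 6 rose and 2 fell adjusted over the list alone (camera adjusted p 0.0901). Of 56 axon guidance genes 0 passed, and 10 were higher and 6 lower adjusted over the list alone (camera adjusted p 0.236; 0.0498 without ethanol replicate 2); PLXNB1 was at 1.84 ± 0.26 and SEMA6A at -1.90 ± 0.34. Of 18 cholinergic genes 0 passed and 5 were higher adjusted over the list alone (camera adjusted p 0.155); CHRM3 was at 1.93 ± 0.28 and COLQ at 2.67 ± 0.46. In Wnt, Notch, BMP and hedgehog signalling, DKK2 rose by 5.89 ± 0.44 and DLK1 fell, out of 57, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p 0.731).

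Markers of the sympathoadrenal cell types shifted unevenly. Chromaffin cell markers were lower (median -0.59; camera adjusted p 0.00085; adjusted p = 0.428 with an estimated correlation), and 4 of 19 members fell, namely DLK1, HTR3A, CHGA and SLC18A1; adjusted over the list alone 2 rose and 5 fell. Schwann cell precursor markers were higher (median 1.43; camera adjusted p 0.00117; adjusted p = 0.428 with an estimated correlation), with 0 of 15 members called (6, 5, 4 and 6 higher without a library) and 7 higher and 1 lower adjusted over the list alone. INSC and SOX8 had 0 reads with ethanol and were at least 47.4-fold and 49.5-fold higher with ATRA. Of 28 adrenergic transcription factors 2 fell, GATA3 by 2.64 ± 0.30 and HAND1 by 2.08 ± 0.26, and 6 rose and 5 fell adjusted over the list alone (camera adjusted p 0.137). Catecholamine synthesis and storage genes were not called (camera adjusted p 0.299), and 1 of 21 members rose and 2 fell. Chromogranin A, CHGA, fell from 2058 ± 640 to 211 ± 34.0 CPM and the vesicular monoamine transporter SLC18A1 fell by 2.16 ± 0.25, while SCG5 rose by 1.73 ± 0.24; adjusted over the list alone 3 rose and 3 fell. Of its measured members 9 are also chromaffin markers.

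Proliferation genes were lower. All 55 G2/M genes and 50 of 51 G1/S genes were lower within both replicate numbers, with medians of -1.28 (-1.61 and -1.08 within replicates) and -1.19 (-1.59 and -0.89). Camera adjusted p was 2.05e-19 and 5.25e-19 (adjusted p = 0.460 and 0.463 with an estimated correlation). The estimated correlation was 0.752 and 0.855, far above the preset 0.01, so these preset p-values are likely too small. Fry did not call either list (adjusted p 0.168 for each, and 0.108 for a change in either direction). With 2 residual degrees of freedom, these non-calls decide little. In these lists 0 members passed edgeR quasi-likelihood over all genes, while adjusted over the list alone 32 of the G2/M and 35 of the G1/S genes were lower. Without a library 1, 46, 33 and 3 G2/M genes and 0, 40, 13 and 7 G1/S genes were called lower; 23 and 15 were with DESeq2, and 47 and 35 with every gene of at least 1 count. With the title suffix as a block, which called 4098 genes in all, 52 G2/M and 48 G1/S genes were called lower (edgeR quasi-likelihood). DESeq2 with that block called 51 and 46 lower. PLK1 was at -1.51 ± 0.26, AURKB at -1.92 ± 0.38, FEN1 at -1.35 ± 0.25 and CHAF1A at -1.35 ± 0.28. Replication-dependent histone genes were lower in all 46 cases (median -1.67; camera adjusted p 9.33e-28; adjusted p = 0.428 with an estimated correlation). Of them 4 fell, with HIST1H2AJ at -2.00 ± 0.27 and HIST1H2AB at -1.91 ± 0.25, and 43 fell adjusted over the list alone. The 4 became 7 with upper quartile factors, 2 with library size alone, 0 with limma-voom or glmTreat, 18 with protein-coding genes, 39 with DESeq2 and 42 with every gene of at least 1 count. With the title suffix as a block they were 45. Without ATRA replicate 1 or 2 they were 23 or 37, and without ethanol replicate 1 or 2 they were 37 or 29. These are near-identical genes whose reads the counting could split. Cell cycle inhibitors were not called (camera adjusted p 0.787), with 2 higher and 3 lower of 28 adjusted over the list alone; SESN3 was at -1.43 ± 0.26 and TP53INP1 had 16.5 ± 0.107 CPM with ethanol and 46.7 ± 18.6 CPM with ATRA.

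Genes of growth were lower by less. MYC targets and ribosome biogenesis genes had a median of -0.56 (camera adjusted p 1.64e-09; adjusted p = 0.273 with an estimated correlation), and 55 of 58 were lower within both replicates. FBL was at -1.25 ± 0.31 and RANBP1 at -0.87 ± 0.24. Cytosolic ribosomal proteins had a median of -0.41, with -0.19 and -0.59 within replicates (camera adjusted p 7.38e-08; adjusted p = 0.522 with an estimated correlation); RPS2 was at -0.81 ± 0.29 and RPS3 at -0.76 ± 0.28. The ribosomal protein list was not called without ethanol replicate 2 (camera adjusted p 0.0728). No member of either list passed singly, over all genes or adjusted over the list alone, while 1 MYC target or ribosome biogenesis gene was called lower in each fit without a library. With the title suffix as a block, 33 MYC target or ribosome biogenesis genes and 13 ribosomal protein genes were called lower (edgeR quasi-likelihood). DESeq2 with that block called 18 and 6 lower. The blocked edgeR fit called 4098 genes in all. The mitochondrially encoded mRNAs were not called (median -0.74, camera adjusted p 0.0762). In the main test 0 of 13 passed, over all genes or adjusted over the list alone. The list was called lower with every gene of at least 1 count (camera adjusted p 0.0288). It was also called lower without ATRA replicate 1 and without ethanol replicate 2, and in both fits some members were called lower singly. With the title suffix as a block 9 members were called lower. MT-ND4 was at -0.89 ± 0.69 and MT-ND4L at -0.82 ± 0.45, in libraries whose mitochondrial ribosomal RNA differed as given above.

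The BCL2 family list was higher (median 0.44; camera adjusted p 0.00064; adjusted p = 0.435 with an estimated correlation), with 0 of 29 members called (3 higher in each fit without a library) and 5 higher adjusted over the list alone; BOK was at 2.47 ± 0.38 and TNFRSF10B at 2.74 ± 0.45. The list was not called without ethanol replicate 1 (camera adjusted p 0.0722). Stress and immediate early genes were not called (camera adjusted p 0.137; 0.0498 without ethanol replicate 2), with 2 of 26 higher adjusted over the list alone; IER3 was at 2.89 ± 0.49 and NFKBIA at -0.93 ± 0.26. Antigen presentation and interferon response (camera adjusted p 0.0756), cholesterol synthesis (0.236) and the unfolded protein and integrated stress response (0.622) were not called either. Without 1 library each of them was called: the first (0.0145) and the second (0.0333) without ATRA replicate 2, and the third (0.0018) without ethanol replicate 1. The first was also called with every gene of at least 1 count (0.0458). In the main test these lists had 0 of 30, 0 of 25 and 0 of 36 members past the threshold, and 0 in each adjusted over the list alone. Some members of each were called singly in the fit without a library that called the list. OAS3 was at -0.93 ± 0.27, OAS1 at 1.36 ± 0.43, EBP at -0.73 ± 0.26, FDFT1 at 0.61 ± 0.27, EIF2AK3 at 1.16 ± 0.24 and PSAT1 at -1.34 ± 0.43.

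**Figure D3:**
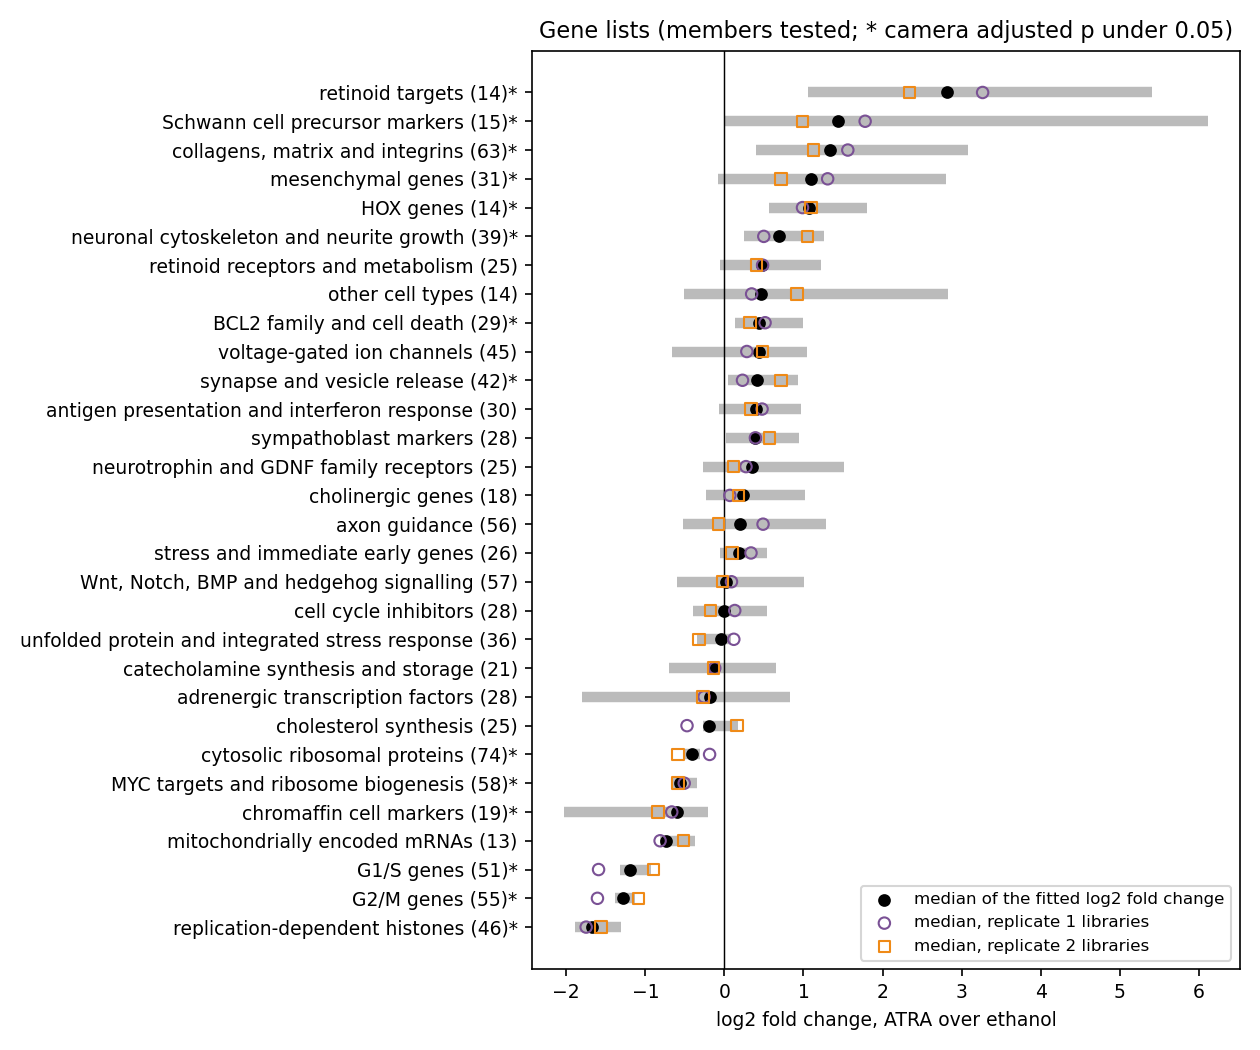
Median log2 fold change, ATRA over ethanol, of the 30 gene lists (black points), the range between the quartiles of their members (grey bars), and medians within replicate 1 (open circles) and replicate 2 (open squares), with the number of members tested in brackets and asterisks for camera adjusted p under 0.05. Retinoid targets stand highest at 2.82 and replication-dependent histones lowest at -1.67.

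Some calls close to the threshold ended with another scaling or filter (edgeR quasi-likelihood): SCG5 with RLE (adjusted p 0.0504), KCNMA1 with upper quartile factors (0.0521), SPOCK3 and HIST1H2AJ with library size alone (0.0531 and 0.0559), and COL3A1 with a filter of 1 CPM in 2 libraries (0.0502). The call of SCG5 also ended with library size alone and without mitochondrially encoded and the 20 most abundant genes. Of the 83 named genes, 25 overlap another gene that was tested, among them RARB, GATA3, DLG2, SULF2, IGFBP7 and SORCS2 of those called, and since the strand setting is not given their counts may hold reads of the other gene. None of the overlapping genes was itself called (edgeR quasi-likelihood).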

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

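Of the alternatives here, DESeq2 with the block was chosen after the data were seen. Counts of called genes (132, with 103 higher and 29 lower) stayed within 1.5 times under the scalings RLE, upper quartile and library size, the filter of 1 CPM, no robust estimation, and removal of mitochondrial and the 20 most abundant genes, which called 118 to 131 of the 132 again, or 132 without robust estimation. They moved to 1821 (1126 higher, 695 lower) with every gene of at least 1 count, 1269 (827, 442) with DESeq2, 50 (43, 7) with limma-voom, 28 (25, 3) with glmTreat and 254 (180, 74) with protein-coding genes. Without 1 library they ranged from 870 to 1442, with 547 to 838 higher and 231 to 604 lower (870 and 1442 without ATRA 1 and 2, 888 and 1227 without ethanol 1 and 2), with the lone library assumed to vary like the other group. The median prior degrees of freedom were 4.03 in the main test, 69.1 without ethanol 1 and infinite without any other library or with every gene of at least 1 count, so those fits borrowed more across genes. Whether that caused their larger counts was not tested, nor was the cause of the other moves. Of the 38 named genes called, limma-voom and glmTreat each left 26 uncalled, while 28 more of the 83 were called with every gene of at least 1 count, 26 with DESeq2, 10 with protein-coding genes and 19 to 25 without 1 library. The share higher was 78.0%, with 77.4% to 79.0% across scalings, 61.8%, 65.2%, 86%, 89.3% and 70.9% for the moved counts in the order above, and 58.1% (without ATRA 2) to 73.45% (without ATRA 1) without 1 library.

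Replicate numbers share only a title suffix. Deviations of same-suffix libraries correlated at 0.632, a hint from the data and not the design. The replicate block called 4098 genes (2325, 1773; 56.7% higher) and 130 of the 132 again, DESeq2 with the block 2629 (1469, 1160). Of the named genes, 37 more were called with the block, MYCN among them (adjusted p 0.0291), and COL3A1 and PTPRU were not (0.0613 and 0.0889, edgeR quasi-likelihood). In the simulation with library differences the block recovered 51% of 2-fold and 97% of 8-fold changes, against 0% and 52% without it, and 16.4% of its calls were false, against 0%. In the one without such differences it recovered 8% and 79%, against 2% and 67%, with 26.3% false, against 12.7%. Camera with the block called 15 lists, adding the mitochondrially encoded mRNAs (0.00141), but 0 with an estimated correlation (0.655 for these). Fry called 0 with the block, the retinoid targets included (0.103). The block leaves 1 residual degree of freedom, on which fry and camera with an estimated correlation could hardly call any list. These non-calls thus decide nothing.

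With an estimated correlation 0 lists were called, and 1 by fry. Between ethanol libraries r was 0.967 with every gene of at least 1 count and 0.942 with the filter of 1 CPM. Direction turned among genes and lists not called, with these ranges when each library was left out: CDKN1A -0.19 (without ATRA 2) to 1.04, ISL1 -0.21 to 0.060 (without ATRA 2), MT-ND4 -1.71 to 0.27 (without ethanol 1), STMN2 -0.14 (without ATRA 2) to 1.37, and TH -0.90 to 0.34 (without ethanol 2). Camera adjusted p ranged from 0.275 to 0.798 for cell cycle inhibitors, which turned without ATRA 1 (0.798) and ethanol 2 (0.446), and from 0.0333 to 0.798 for cholesterol synthesis, which turned without ATRA 1 (0.798). It ranged from 0.0018 to 0.640 for the unfolded protein and integrated stress response, which turned without ethanol 2 (0.0987). The cause was not tested. Without 1 library, 5, 2, 1 and 5 lists were gained (ATRA 1 and 2, ethanol 1 and 2). The list calls that ended without a library were neuronal cytoskeleton (0.0646) and synapse (0.158) without ATRA 2, BCL2 family (0.0722) without ethanol 1, and synapse (0.0762) and ribosomal proteins (0.0728) without ethanol 2. A gene at 3 counts stood between 0.149 and 0.231 CPM, which limits what can be seen below that level.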

Other observations

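Both tests of fibroblast transcripts and the permutation over pairs that do not overlap were chosen after the result was seen, and the neighbouring genes were noticed in these data before they were tested. The genes in this first paragraph were also chosen after their values were seen. Outside the lists, these genes rose (edgeR quasi-likelihood). DUSP6, a phosphatase of the MAP kinase pathway, rose from 13.2 ± 8.10 to 399 ± 3.65 CPM (SD, n = 2). PLAT, tissue plasminogen activator, rose from 42.4 ± 4.40 to 662 ± 263 CPM. IL33, a cytokine, had 0 reads with ethanol and was at least 54.4-fold higher.

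Libraries split by the suffix of their titles as well as by treatment. If depletion of ribosomal and small RNA were the whole difference, the split should vanish among protein-coding genes rescaled to their own total. The correlation of same-suffix deviations there was 0.568 (interval 0.547 to 0.589), and 0.542 (0.517 to 0.566) after a trend on GC content and transcript length was removed, which argues against either as the whole cause. The intervals came from resampling genes, which are not independent replicates, and do not cover variation between libraries. A difference between culture or library batches may remain, and no biological explanation was tested.

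Matrix and mesenchymal genes were higher with ATRA. Of 10 abundant fibroblast genes 8 were higher within both replicates, COL1A2 among them at 5 and 1 reads with ATRA against 2 and 0, but 7 of the 10 belong to the lists to be explained, so this count decides nothing. Fibroblast-like cells carried in should bring all 10. COL3A1 gained 69.1 CPM, while 4 of the other 9 gained under 0.1 times its gain within both replicates (COL1A2 0.122, POSTN 0.209, DCN -80.9 and LUM -65.0 CPM). DCN and LUM were already high with ethanol (DCN 139 and 310, LUM 39.8 and 126 CPM in replicates 1 and 2) and fell, so they cannot show such a gain. COL1A2 and POSTN stayed nearly absent, but the bounds of this test were set knowing the values, so it does not decide the source. A shift of the cells themselves stays open: of 16 measured mesenchymal transcription factors and cofactors 56.25% were higher within both replicates, against 38.3% of all genes, and 4 were lower within both, with a median log2 fold change of 0.27. Of the 16, 0 were called and 8 had an unadjusted p under 0.05 in either direction (edgeR quasi-likelihood), and the share higher lay between the bounds set for it.

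Genes that rose may lie next to each other more often than by chance, which is a hypothesis from these data. Neighbours here are genes that follow each other among the 14816 tested genes with a place in the gene order. Untested genes between them were skipped. Among 90 risen genes with a place in the gene order, 5 neighbouring pairs were found against a mean of 0.535 in 100000 shuffles (permutation p 0.0003): CALCB with CALCA, IGSF10 with SUCNR1, HTN3 with HTN1, HTN1 with ODAM, and STARD4-AS1 with NREP. Reads shared between similar genes could account for part, since 3 of the 5 pairs share a stretch of 50 bases, and overlapping gene models for 2. Over pairs that do not overlap, 3 were found against a mean of 0.435 (permutation p 0.0092). HTN3 with HTN1 is among them and shares such a stretch, so shared reads are not removed from this count. Since the pattern was noticed in these same calls, neither permutation p can support it. What links IGSF10 with SUCNR1, and HTN1 with ODAM, which share no such stretch, was not tested.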
